A study of Mus musculus with 6 samples.

How the data were processed

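RNA sequencing was read from 6 deposited tables, 1 per library, of mouse soleus in 3 groups of 2: innervated wild type (WT), WT 3 days after denervation, and 3-day denervated soleus of mice labelled as lacking both Dach2 and Hdac9. Groups were taken from the sample titles. The titles give no replicate numbers, so replicates were numbered in accession order, and nothing in the labels says that they came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical. Total RNA was taken with a column kit and treated with DNase, and polyadenylated RNA was sequenced, per the labels.

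The submitters' processing notes name CASAVA 1.8.2, Trim Galore 0.2.1, Bowtie2 2.0.0.7, TopHat2 2.0.3, Cuffdiff 2.0.2 and build mm9. Their roles and order, the annotation and the strand setting are not given in the sources used here. Per the file headers, each table holds FPKM made by the authors, which scales a gene's fragments by its transcript length and by a factor of the library. A further column holds a signal of externally scaled fragments, per the file headers. In each library that column was the raw fragments times 1 factor, to a relative deviation of at most 8.81e-06. For Gapdh and Myog, FPKM per fragment followed that factor across libraries more closely than it followed the library's total. The factor was 1.1789 in innervated and 0.6643 in denervated WT replicate 1, where Gapdh had 726 FPKM from 29350 fragments and 420 from 30967. FPKM levels therefore do not give a gene's share of its library's total. Per the file headers, the last column holds raw fragments, estimated counts of which 88.4% to 89.0% were whole within 1e-06. How the authors split fragments among close copies, overlapping genes or antisense partners is not stated, so values of such genes are uncertain. Each table lists every gene 3 times in 65415 lines, and 21805 distinct entries remained. They carry 21572 symbols, and entries of 1 symbol were summed (149 symbols). The 197 joined entries that list several symbols were kept under the joined name. Coordinates are those of the files on mm9, and whether starts count from 0 is not stated in them.

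The test planned before the data were examined was limma on log2(FPKM + 0.5). Because the files also hold estimated counts, the main test was instead edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on those counts rounded to whole numbers, with TMM scaling, all 6 libraries in 1 fit of group means, and genes of mean FPKM of at least 0.5, which left 12247. The planned limma fit (limma 3.58.1) is an alternative. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The SE of a log2 fold change is its size divided by the square root of its F value. The fit left 3 residual degrees of freedom per gene, with a common coefficient of biological variation of 0.222.

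Totals ran from 25529434 to 46305449 fragments. Counts were simulated with the denervated WT means in every group and the real library sizes, with 200 changed genes in each of 5 data sets. For denervated against innervated WT (12208 genes) the test recovered 26.2% of 2-fold and 88.6% of 4-fold changes, with a mean of 12.6 false calls. For DKO-labelled against WT, both denervated (12206 genes), it recovered 19.2% and 85.8%, with a mean of 7.6 false calls. Recovery after Benjamini-Hochberg adjustment depends on how many genes change. The simulations changed 200, whereas the data gave 3512 and 5 called genes, so these percentages do not carry over to the data directly. Floors for a group at 0 used 3 fragments over the group and cover counting error only. The 2 libraries of each group differed by more than counting noise, with chi-square values per degree of freedom of 31.6, 163 and 64.7, so each was counted as a library of its own.

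The genes named were chosen by a rule fixed with the planned test: the genes of the series title and Gapdh; in each comparison the 8 genes of highest and the 8 of lowest change among called genes whose libraries separate the groups, filled up by the smallest unadjusted p and passing over predicted or unnamed transcripts; and up to 4 called members of each gene list, or up to 2 of smallest p. Of the genes both comparisons call, up to 5 per pattern were named. Members of a list given without a value are those its count refers to. Exceptions are said where they stand, and some genes that the rule selects are not reported here.

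The 38 gene lists were fixed at the same time and cover muscle, metabolism, stress and the other cell types of a muscle. They hold 793 entries, with a gene counted once in each list that names it. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. That left 37, since lymphocyte markers had fewer tested members. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and compares them with no other genes. Some genes, such as Ncam1, Gdnf, Cdh2, Id2 and Dcn, are in more than 1 list, and muscle fibres also express some markers of other cells.

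The limma alternatives changed test, input and scaling together: the planned fit, and from it pseudocounts of 0.1 and 1 and quantile normalization. The others changed 1 choice of the edgeR fit at a time: no filter or mean FPKM of at least 2; median ratio scaling; only the 4 libraries compared; no trend or a robust fit; the runs of sample numbers as a block; the highest entry per symbol; and each library left out in turn. DESeq2 1.42.0 and the authors' external scale were added after the data were seen. Copies of Rpl35 were searched with BLAST+ 2.17.0 in the GRCm38 transcripts of GENCODE. Figures were drawn with matplotlib 3.10.9.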

Results

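Polyadenylated RNA of the soleus, a hindlimb muscle rich in slow fibres, was sequenced from adult C57BL/6 mice. The 6 libraries formed 3 groups of 2: innervated soleus of wild-type (WT) mice, WT soleus 3 days after denervation (removal of its nerve supply), and denervated soleus of mice labelled as lacking both Dach2 and Hdac9, also at 3 days. Dach2 is a transcriptional co-factor and Hdac9 a class II histone deacetylase. Innervated knockout muscle was not analysed here. The first library of each group had the sample numbers 14043 to 14045 and the second 14049 to 14051, so the libraries fell into 2 runs of consecutive numbers, each with 1 library per group.

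The libraries held 31671100 and 25529434 assigned fragments in innervated WT muscle, 46305449 and 30489977 in denervated WT muscle, and 32380082 and 30510780 in the libraries labelled double knockout (DKO-labelled). Expression is given as the authors' FPKM, mean ± SD over the 2 libraries of a group. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test on the deposited fragment counts, with Benjamini-Hochberg adjusted p over 12247 genes. The first principal component held 73% of the variance and separated innervated from denervated muscle. The second held 13%, and on it denervated WT replicate 2 stood apart at 43.3, with the other libraries between -27.9 and 8.8. Across genes, which are not independent replicates, log2 expression in the 2 libraries of a group correlated at 0.988 in innervated WT, 0.966 in denervated WT and 0.982 in DKO-labelled muscle.

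Dach2 (X: 110411864 to 110949995) and Hdac9 (12: 35056361 to 35213754), the genes named as deleted, were read first in every library. Myog (1: 136186580 to 136189125) encodes the muscle transcription factor myogenin, and Gdf5 (2: 155766760 to 155771100) a BMP family ligand. These are whole gene loci on build mm9 as the files list them. Dach2 was at 3.85 and 4.29 FPKM in innervated WT, 0.519 and 0.536 in denervated WT, and 0.961 and 0.681 in DKO-labelled libraries, so it was lower in DKO-labelled than in innervated WT libraries but not lower than in denervated WT, the group of the same treatment. Hdac9 was at 4.10 and 3.14 FPKM in innervated WT, 1.83 and 0.285 in denervated WT, and 0.534 and 0.181 in DKO-labelled libraries. A value over a whole gene counts fragments from exons outside a deleted part, so it does not check the deletion, and the group is called DKO-labelled throughout.

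**Figure D1:**
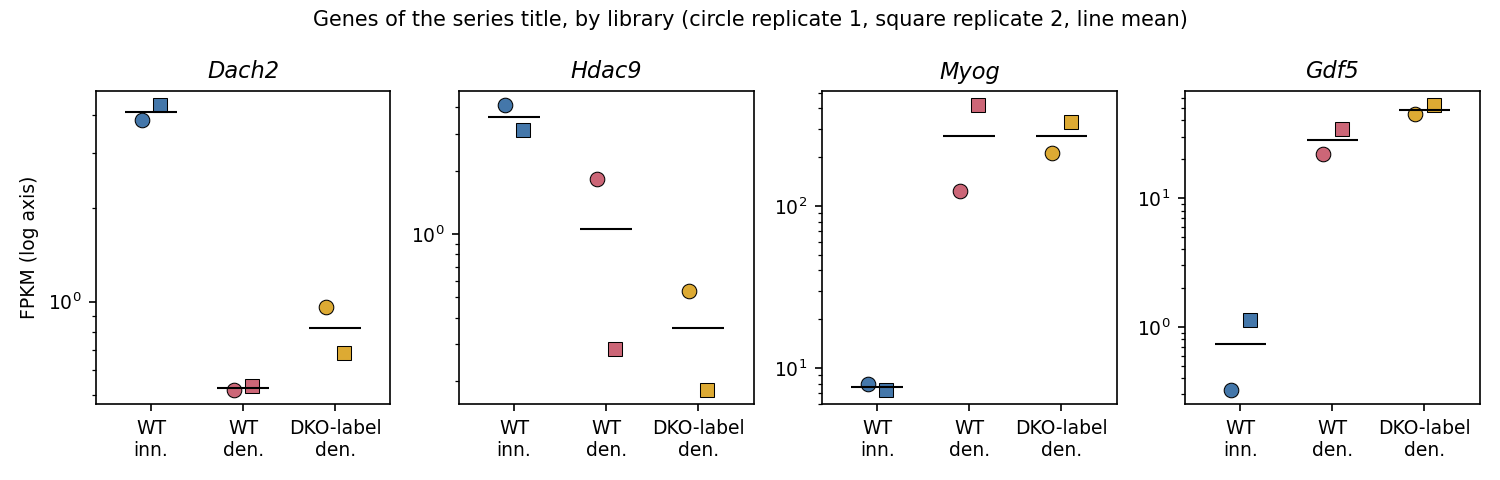
FPKM (log axis) of Dach2, Hdac9, Myog and Gdf5 in each library of innervated WT, denervated WT and DKO-labelled denervated soleus (circle, replicate 1; square, replicate 2; line, group mean, n = 2). Myog lay at 8.02 and 7.32 in innervated WT libraries and at 124 or above in each denervated library, while Dach2 lay at 3.85 and 4.29 in innervated WT libraries and at 0.961 or below in each denervated library.

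The first comparison asked which genes differ between denervated and innervated WT soleus. Myog rose 37.5-fold, from 7.67 ± 0.493 to 271 ± 208 FPKM (SD, n = 2), and Gdf5 rose 42.2-fold, from 0.731 ± 0.575 to 28.0 ± 8.83 FPKM. Dach2 fell 8.35-fold, from 4.07 ± 0.308 to 0.528 ± 0.0117 FPKM. At a preset correlation, camera called the lists of neuromuscular junction, proteasome and ribosome genes higher, and those of mitochondrial respiration, fatty acid use, glycolysis and both slow and fast fibres lower. All these calls were lost with an estimated correlation (adjusted p = 0.298 to 0.475). In all, 1759 genes rose, 1004 of them at least 2-fold, and 1753 fell, 1163 of them at least 2-fold (edgeR, adjusted p under 0.05).

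Among the genes of the series title, the log2 changes on denervation were 5.23 ± 0.63 for Myog (edgeR adjusted p = 0.00456), 5.40 ± 0.57 for Gdf5 (adjusted p = 0.00335) and -3.06 ± 0.24 for Dach2 (adjusted p = 0.00185). Within the runs of sample numbers, the first and second libraries gave 4.02 and 5.93 for Myog, 6.07 and 5.0 for Gdf5, and -3.03 and -3.05 for Dach2. Hdac9 lay lower in both denervated libraries, at -1.74 ± 0.82, but did not pass the test (adjusted p = 0.151), and its difference was -1.15 in the first run and -3.38 in the second. With the runs as a block it passed, at -2.2 with an adjusted p of 0.022. Without denervated WT replicate 1 the Hdac9 value was -3.65 with an adjusted p of 0.008, the lowest over its 19 alternatives, where the highest was 0.386. Gapdh, a glycolytic enzyme often used as a reference gene, fell by 0.66 ± 0.17 on the log2 scale (adjusted p = 0.0305), a call lost in limma with quantile normalization and without innervated WT replicate 1 or 2 or denervated WT replicate 2.

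The largest increases among separated, called genes included the simple epithelial keratins Krt8 and Krt18, which rose by log2 8.87 ± 0.72 and 7.43 ± 0.87 (edgeR adjusted p = 0.00221 and 0.00420), and the transporter gene Slc10a4, which rose by 8.66 ± 1.16 (adjusted p = 0.00575). U90926 had 0 fragments over both innervated libraries and 477 over both denervated WT libraries, which makes it at least 98.5-fold higher against a floor of 3 fragments over the group. Hamp2 and Dppa5a, also at 0 rounded fragments in innervated muscle, had 65 each and were at least 13.4-fold higher, though limma did not call Dppa5a with a pseudocount of 1 or quantile normalization. Orm2, an acute-phase protein gene, had 3 fragments in innervated and 2628 in denervated WT muscle. Over both DKO-labelled libraries, also denervated, U90926 had only 7 fragments. Its log2 difference from denervated WT was -5.76 (edgeR unadjusted p = 0.000942), which did not pass after adjustment.

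The largest decreases were those of the potassium channel subunit Kcng4 (log2 -6.81 ± 0.44, edgeR adjusted p = 0.00176), the ribosomal protein gene Rpl35 (-6.48 ± 0.28, adjusted p = 0.000598) and the channel subunit Lrrc52 (-6.18 ± 0.34, adjusted p = 0.00115). Atp1b4, AI593442, Sec14l5, Tmem233 and Plcd4 fell by between 27.5-fold and 39.9-fold. Rpl35 has copies of similar coding sequence in the genome, so its value is uncertain.

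Of 23 tested genes of the neuromuscular junction, 12 rose, 3 fell and 8 did not pass (14 and 4, adjusted over the list alone). The acetylcholine receptor subunits Chrng, the fetal form, Chrnd and Chrna1 rose 105-fold, 19.1-fold and 10.8-fold. Chrnb1, the receptor kinase Musk and its partners Dok7 and Lrp4 rose too, while the adult subunit Chrne, the acetylcholinesterase Ache and its collagen tail Colq fell. The list was called higher by camera (median log2 0.99, adjusted p = 4.25e-09), with adjusted p = 0.298 with an estimated correlation. Of 15 myogenic regulators, 6 rose and 0 fell (6 and 0, adjusted over the list alone), among them Myod1 (16.0-fold), Myf6 (10.4-fold) and Id2 (7.23-fold). That list was higher at a median of 0.24 (camera adjusted p = 0.00154; adjusted p = 0.433 with an estimated correlation). Developmental muscle genes, those of fetal or regenerating fibres, rose at 8 of 15 and fell at 2 (9 and 3, adjusted over the list alone). The fusion gene Tmem8c rose 21.2-fold, the adhesion molecule Ncam1 8.64-fold and Peg3 6.22-fold, while Myh8 and Mest fell (camera adjusted p = 0.00372; adjusted p = 0.565 with an estimated correlation). That call was lost without denervated WT replicate 1 and in limma with quantile normalization, and the list's median lay 0.97 higher in that library than in replicate 2.

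Of 8 class II histone deacetylase and Dach genes, Hdac4 rose and Dach1, Dach2, Hdac5 and Hdac7 fell (1 and 4, adjusted over the list alone). Hdac7, Hdac5 and Dach1 fell 2.67-fold, 2.50-fold and 2.13-fold, and for Hdac5 and Dach1 the call was lost in 3 alternatives each and in 5 more that leave out a library. The list was lower at a median of -1.21 (camera adjusted p = 0.0287; adjusted p = 0.475 with an estimated correlation), a call kept in 13 of 19 alternatives. It was lost in all 4 limma fits, the planned test among them, at a mean FPKM of at least 2, and without denervated WT replicate 2. In BMP and GDF signalling, 7 of 28 genes rose and 1 fell (7 and 3, adjusted over the list alone), with Gdf6 at 11.2-fold and the BMP antagonist Chrd at 3.50-fold higher and Bmp6 lower. Limma did not call Gdf6 with a pseudocount of 1 or quantile normalization. As a list it was not called by camera (adjusted p = 0.159) but was by fry (adjusted p = 0.0477).

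Proteasome subunits rose at 21 of 30 and fell at 0 (29 and 0, adjusted over the list alone), with Psmd8 2.92-fold, Psmc4 2.37-fold and Psma5 2.30-fold higher. The list median was 0.87 (camera adjusted p = 3.13e-09; adjusted p = 0.475 with an estimated correlation). Of 19 atrophy ubiquitin ligase and FoxO genes, 4 rose and 2 fell (4 and 3, adjusted over the list alone), and the list was not called (camera adjusted p = 0.630). Trim63, the ubiquitin ligase MuRF1, rose 1.87-fold, the ligase Fbxo30 1.74-fold and the translation repressor Eif4ebp1 4.25-fold, while Fbxo32, the ligase atrogin-1, was at -0.05 ± 0.26 (edgeR adjusted p = 0.894). Of 20 autophagy and lysosome genes, 6 rose and 1 fell (8 and 1, adjusted over the list alone), with the cathepsins Ctsl and Ctsd 3.63-fold and 2.18-fold higher, but the list did not pass (camera adjusted p = 0.0650). Ribosomal proteins rose at 57 of 60 and fell at 1, Rpl35 (59 and 1, adjusted over the list alone). Rpl3 rose 8.15-fold and Rpl12 2.97-fold, and the list median was 1.02 (camera adjusted p = 2.58e-18; adjusted p = 0.475 with an estimated correlation). Processed copies of ribosomal protein genes can share their fragments, so these values are uncertain.

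Slow fibre genes fell at 8 of 13 and rose at 0 (10 and 1, adjusted over the list alone). The slow myosin heavy chain Myh7 fell from 1440 ± 370 to 268 ± 229 FPKM (4.99-fold), its light chain Myl2 5.61-fold and the troponin Tnnc1 3.19-fold. Fast fibre genes fell at 9 of 17 and rose at 1 (10 and 1, adjusted over the list alone), with Myh2, Myoz1 and Mylk2 lower by 4.25-fold, 4.04-fold and 3.53-fold and Actn3 higher by 4.45-fold. The medians were -1.46 for slow and -1.19 for fast fibre genes (camera adjusted p = 4e-05 and 8.33e-05; adjusted p = 0.433 and 0.475 with an estimated correlation). The fast fibre call was lost in limma with quantile normalization, as were those of Myh7, Tnnc1 and Myh2. In a fit of the 4 WT libraries alone Myh7 and Actn3 lost theirs, and with 1 library left out Myh7 lost it in 4 of 6 fits, Actn3 in 5 and Myh2 in 3. Within the runs Myh7 was at -1.36 and -3.88 and Actn3 at 3.57 and 1.38. Excitation and calcium release genes rose at 7 of 20 and fell at 5 (7 and 9, adjusted over the list alone). The potassium channel Kcnn3 rose 14.3-fold and phospholamban, Pln, 4.54-fold, while the chloride channel Clcn1 fell 5.54-fold. Camera called that list higher (adjusted p = 0.0400; adjusted p = 0.475 with an estimated correlation) and its mean was 0.29, but its median was -0.41. The call was lost in 12 of 19 alternatives, among them all 4 limma fits, the fit with the runs as a block and those without innervated WT replicate 1 or 2, denervated WT replicate 1 or either DKO-labelled library.

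Oxidative phosphorylation genes fell at 57 of 65 and rose at 0 (62 and 0, adjusted over the list alone), with Sdhc 3.19-fold, Ndufb10 2.95-fold and Ndufs7 2.81-fold lower. The tricarboxylic acid (TCA) cycle fell at 19 of 21 genes (20, adjusted over the list alone), led by Idh2 at 8.34-fold and Mdh1 at 7.52-fold lower. Fatty acid uptake and oxidation fell at 20 of 27 (23, adjusted over the list alone), with the mitochondrial carrier Ucp3 9.54-fold, the lipase Lpl 8.92-fold and the fatty acid binding protein Fabp3 8.01-fold lower. Glycolysis and glycogen genes fell at 15 of 25 and rose at 0 (17 and 2, adjusted over the list alone), with Pfkfb1 12.7-fold and the glucose transporter Slc2a4 6.45-fold lower. The 4 list medians were -0.91, -0.98, -1.31 and -1.21, with camera adjusted p of 1.05e-18, 5.1e-12, 1.9e-14 and 9.81e-09. With an estimated correlation the adjusted p was 0.475, 0.320, 0.333 and 0.433. In polyamine metabolism Odc1 and Srm rose 6.82-fold and 2.76-fold, 2 of 9 genes (1, adjusted over the list alone), and the list was not called (camera adjusted p = 0.773, direction up, with a median of -0.11 and a mean of 0.32). The Srm call (edgeR adjusted p = 0.046) was lost in 7 alternatives, among them the planned limma test, and in 5 more that leave out a library.

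Of 16 genes of denervation-associated stress and growth arrest, 8 rose and 5 fell (8 and 5, adjusted over the list alone). Ankrd1 rose 74.0-fold, the transcription factor Runx1 50.4-fold, Gadd45a 50.1-fold and the metallothionein Mt2 34.9-fold (list median 1.03, camera adjusted p = 0.00245; adjusted p = 0.433 with an estimated correlation). That call was kept in 15 of 19 alternatives and lost in all 4 limma fits, the planned test among them. Immediate early genes fell at 8 of 18 and rose at 1, Myc at 9.45-fold (10 and 2, adjusted over the list alone). Nr4a1, Egr3 and Egr1 fell 19.5-fold, 15.8-fold and 11.2-fold (camera adjusted p = 0.000532; adjusted p = 0.298 with an estimated correlation). Interferon response genes fell at 9 of 18 and rose at 0 (14 and 0, adjusted over the list alone), with Gbp3 3.51-fold lower (camera adjusted p = 4.2e-05; adjusted p = 0.475 with an estimated correlation). Their median lay 0.90 higher in denervated WT replicate 1 than in replicate 2. Cell cycle genes rose at 4 of 13 (5, adjusted over the list alone), with Rrm2 47.9-fold, Mcm5 3.48-fold and Aurka 2.42-fold higher (camera adjusted p = 0.00154; adjusted p = 0.475 with an estimated correlation). The planned limma test called neither Mcm5 nor Aurka, and the Aurka call was lost in 4 alternatives and in 5 more that leave out a library. The median of the list was 0.83 higher in denervated WT replicate 1, and its call was lost without that library.

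The integrated stress response list was not called (camera adjusted p = 0.985, direction down, median -0.25, mean 0.07), with 3 of 17 genes higher and 3 lower (3 and 3, adjusted over the list alone): the amino acid transporter Slc7a5 rose 15.5-fold and Ddit3 fell 2.75-fold. Of 16 circadian clock genes, Clock rose 2.25-fold and Nr1d1 and Hlf fell 3.33-fold and 2.38-fold (1 and 2, adjusted over the list alone; camera adjusted p = 0.366). The Hlf call was lost in limma with quantile normalization. Among 18 trophic and guidance factors, 3 rose and 3 fell (4 and 4, adjusted over the list alone), with the neurotrophic factor Gdnf 10.9-fold higher and Vegfa 3.72-fold lower (camera adjusted p = 0.777). Sex-linked genes, 4 tested, showed 0 higher and 0 lower (0 and 0, adjusted over the list alone; camera adjusted p = 0.777).

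Markers of other cell types moved as well. Myelinating Schwann cell markers fell at 8 of 14 and rose at 1, Gjb1 (10 and 2, adjusted over the list alone), with Cldn19 and Prx 4.66-fold and 3.14-fold lower. Repair Schwann cell markers rose at 6 of 8 (6, adjusted over the list alone), with Gdnf, Ncam1, which muscle also expresses, Runx2 (6.33-fold) and Tnfrsf12a (5.72-fold) among them. The camera adjusted p was 0.000844 and 1.28e-05, and with an estimated correlation the adjusted p was 0.298 for each. Macrophage and monocyte markers rose at 4 of 22 (4, adjusted over the list alone), Lgals3 at 9.94-fold and Cd68 at 3.00-fold (camera adjusted p = 0.0187; adjusted p = 0.675 with an estimated correlation). That call was lost without denervated WT replicate 1 and without innervated WT replicate 2. Of 5 neutrophil markers, Lcn2 and S100a8 rose 49.2-fold and 11.1-fold (2, adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0736) but was called with the runs as a block and in 5 of 19 alternatives in all. Its median lay 1.29 lower in denervated WT replicate 1 than in replicate 2.

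Endothelial markers fell at 10 of 16 (12, adjusted over the list alone), with Kdr 3.60-fold and Cldn5 2.52-fold lower, and smooth muscle and pericyte markers at 8 of 13 (10, adjusted over the list alone), with Lmod1 3.07-fold and Acta2 2.75-fold lower. Adipocyte markers fell at 9 of 14 (10, adjusted over the list alone), with the lipid droplet proteins Plin1 and Plin4 7.32-fold and 6.53-fold lower. The Plin4 call (edgeR adjusted p = 0.0475) was lost in a fit of the 4 WT libraries alone and in 4 of 6 fits with 1 library left out, and its run values were -4.43 and -2.04. For the endothelial, smooth muscle and adipocyte lists the camera adjusted p was 3.21e-05, 0.000193 and 8.42e-05, and with an estimated correlation the adjusted p was 0.475 for each. Extracellular matrix genes fell at 2 of 29, Thbs2 and Dcn, and rose at 1, Timp1 at 5.12-fold (0 and 0, adjusted over the list alone), while the list median was -1.05 (camera adjusted p = 0.00528; adjusted p = 0.675 with an estimated correlation). The Dcn call (edgeR adjusted p = 0.0469) was lost in 4 alternatives and in 5 more that leave out a library. Fibro-adipogenic progenitor markers fell at 5 of 14 and rose at 1, Cxcl14 (7 and 1, adjusted over the list alone), with Clec3b 3.97-fold lower (camera adjusted p = 0.0414; adjusted p = 0.675 with an estimated correlation). Without denervated WT replicate 2 or innervated WT replicate 1 both list calls were lost, and the progenitor call also without DKO-labelled replicate 1, at a mean FPKM of at least 2 and in a fit of the 4 WT libraries alone. Denervated WT replicate 1 exceeded replicate 2 by a median of 1.66 for extracellular matrix genes and 0.96 for progenitor markers.

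Tendon and cartilage markers fell at 5 of 11, with Chad 4.15-fold, Fmod 4.03-fold and Tnmd 3.99-fold lower, and rose at 1, Scx at 4.62-fold (5 and 2, adjusted over the list alone), but the list did not pass (camera adjusted p = 0.0736). Their median lay 1.5 higher in denervated WT replicate 1 than in replicate 2, and the Tnmd call was lost in a fit of the 4 WT libraries alone and in 4 of 6 fits with 1 library left out. Of 12 satellite cell markers, Cdh15 rose 1.93-fold and Heyl and Chodl fell 1.95-fold and 1.8-fold (1 and 0, adjusted over the list alone; camera adjusted p = 0.985). The Chodl call was lost in 2 alternatives and in 5 more that leave out a library, and the Heyl call in 3 that do. Of 5 red blood cell markers, Bpgm fell 2.04-fold (1, adjusted over the list alone), and the list was not called (camera adjusted p = 0.807, direction down, with a median of 0.31 and a mean of 0.15). Its median was 1.63 lower in denervated WT replicate 1 than in replicate 2.

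**Figure D2:**
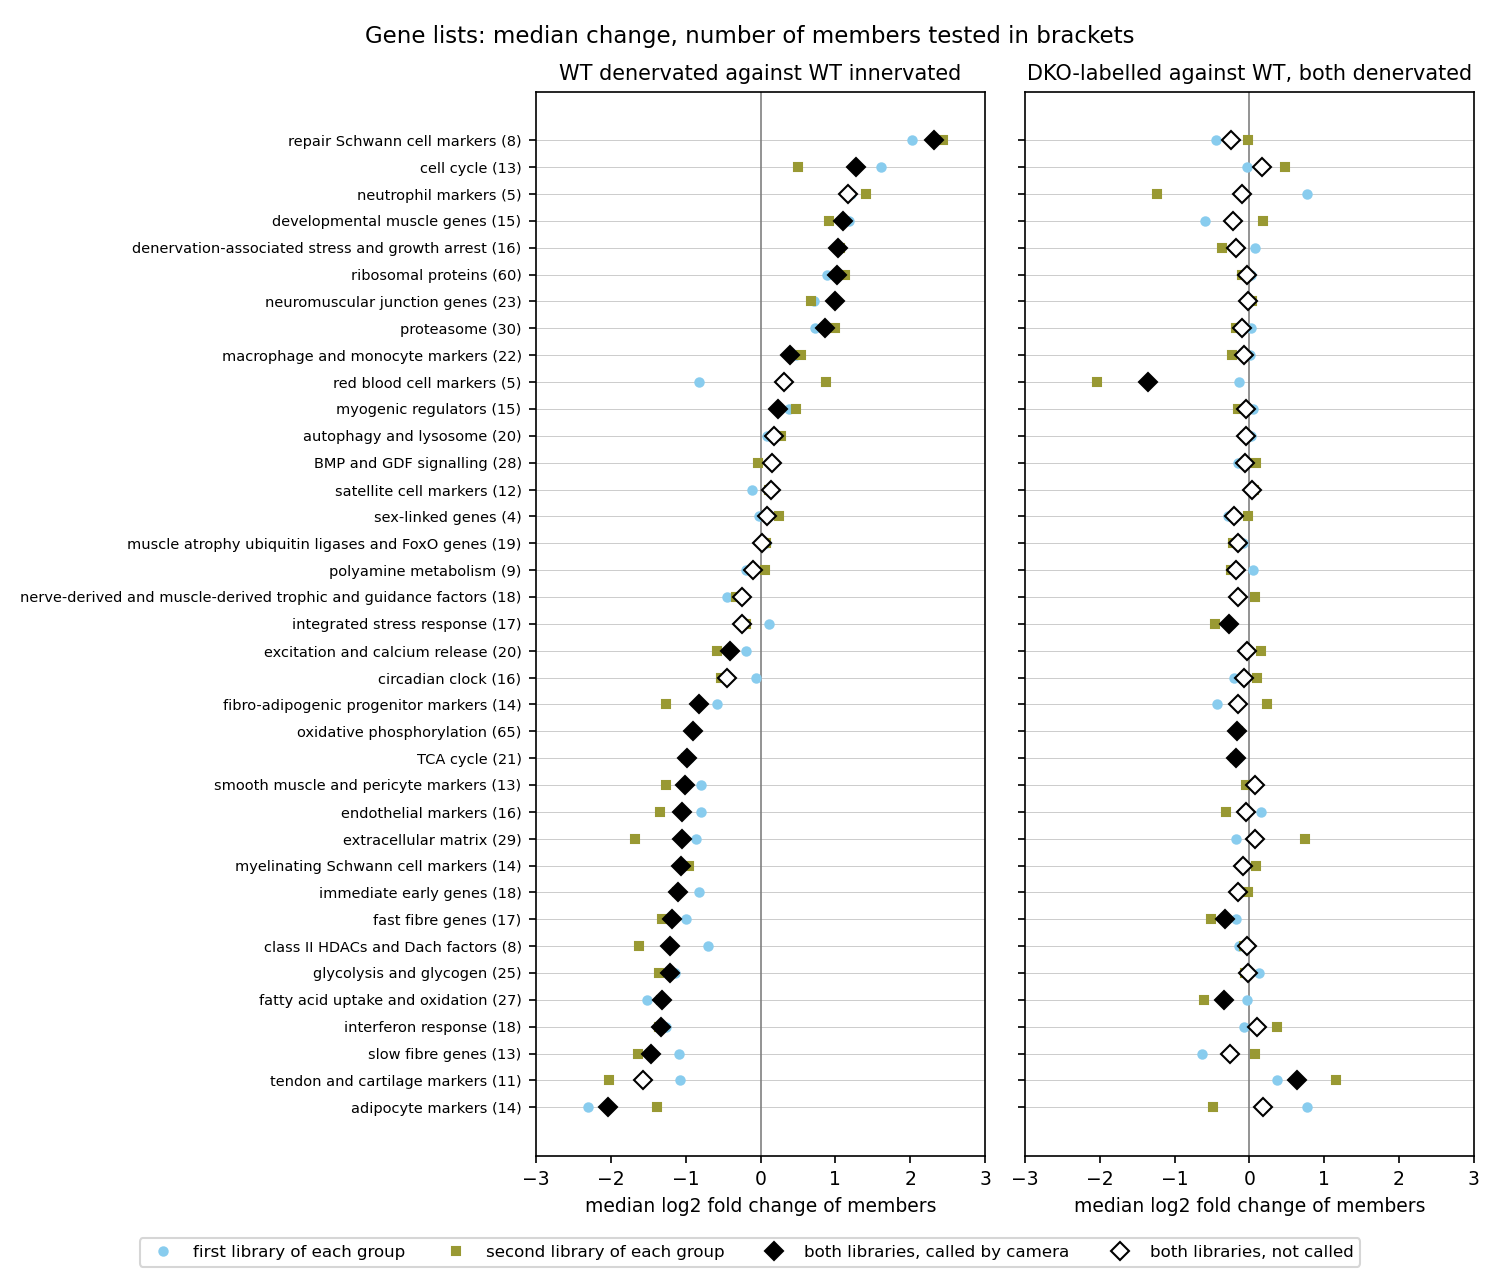
Median log2 fold change of the tested members of each gene list, denervated against innervated WT soleus (left) and DKO-labelled against WT, both denervated (right). Diamonds use both libraries (filled where camera called the list), circles the first and squares the second library of each group; in the left panel 25 of 37 lists are filled and in the right panel 7.

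Camera, which compares the genes of a list with all other tested genes at a preset correlation of 0.01, called 10 lists higher and 15 lower of 37. With an estimated correlation 0 lists were called, the lowest adjusted p being 0.298. The rotation test fry called 11, of which 10 were also called by camera, the other being BMP and GDF signalling. All 3512 called genes changed in the same direction in both runs of sample numbers, which calling them from these same libraries nearly fixes. Of all tested genes, 71.1% had both denervated WT libraries on 1 side of both innervated ones, where 33.3% would by chance. By edgeR 5374 genes had an unadjusted p under 0.05 where 612 would by chance. Leaving out innervated WT replicate 1 or 2 left 468 and 202 called genes, and leaving out denervated WT replicate 1 gave 5357. Of 144 named calls over both comparisons, the title genes apart, 31 were kept in every alternative that gave a value. Without innervated WT replicate 1 or 2, Myog was at 5.30 and 5.16 with an adjusted p of 0.0512 and 0.0634, where its other alternatives went down to 1.19e-22.

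The second comparison asked which genes differ between DKO-labelled and WT soleus, both denervated for 3 days, with directions drawn from the labels. Gdpd3, a glycerophosphodiester phosphodiesterase, rose 45.7-fold, from 0.467 ± 0.146 FPKM in WT to 21.8 ± 2.82 in DKO-labelled libraries (SD, n = 2). Dusp4, a phosphatase of MAP kinases, rose 31.2-fold, from 0.506 ± 0.0391 to 15.4 ± 3.29 FPKM. Rab6b, a small GTPase of vesicle traffic, fell 13.6-fold, from 2.27 ± 0.225 to 0.166 ± 0.0513 FPKM. Myog was at 271 ± 208 and 270 ± 81.8 FPKM (adjusted p = 0.998). Gdf5, at 28.0 ± 8.83 and 48.5 ± 5.58 FPKM, was higher in both DKO-labelled than in both WT libraries but did not pass the test (adjusted p = 0.926).

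In this comparison 3 genes rose and 2 fell of 12247 (edgeR adjusted p under 0.05). Gdpd3 (7: 133909927 to 133919159) changed by log2 5.51 ± 0.32 (adjusted p = 0.0124) and Dusp4 (8: 35870663 to 35882948) by 4.97 ± 0.32 (adjusted p = 0.0133). Rab6b (9: 103014403 to 103087600) was at -3.77 ± 0.28 (adjusted p = 0.0199). The other called genes fall outside the rule for named genes and were picked after their values were seen: the joined entry Serpina3f,Serpina3g, of serine protease inhibitors, at 4.98 ± 0.44, and 1700066B19Rik at -2.82 ± 0.26 (adjusted p = 0.0478 for each). With the runs as a block both of these lost their calls, at an adjusted p of 0.056 each, and the calls of Gdpd3, Dusp4 and Rab6b were kept. For each called gene both DKO-labelled libraries lay on the same side of both WT libraries, which calling them from these same libraries nearly fixes. Within the runs, the values were 5.0 and 5.86 for Gdpd3, 4.75 and 5.04 for Dusp4, and -3.53 and -3.93 for Rab6b.

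The genes of the title did not pass between DKO-labelled and WT denervated muscle. Dach2 was at 0.64 ± 0.22 (edgeR adjusted p = 0.727), Hdac9 at -1.62 ± 0.85 (adjusted p = 0.918), Myog at 0.03 ± 0.53 (adjusted p = 0.998) and Gdf5 at 0.84 ± 0.45 (adjusted p = 0.926). The 95% intervals ran from -1.23 to 1.30 for Myog and from -0.25 to 1.93 for Gdf5. Within the runs Gdf5 was at 1.08 and 0.66 and Myog at 0.81 and -0.31. Without denervated WT replicate 1 the value was 0.28 for Hdac9 and -0.59 for Myog, and without DKO-labelled replicate 2 it was -0.32 for Myog, so their directions turned. Gapdh was at -0.13 ± 0.17 (adjusted p = 0.977).

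Genes with the next smallest p did not pass the test and are given as values. The class I histocompatibility gene H2-K1 was at 35.6 ± 1.93 FPKM in DKO-labelled and 9.29 ± 2.08 in WT libraries, and its relative H2-Q2 at 0.0894 ± 0.0365 and 1.84 ± 0.397 (edgeR adjusted p = 0.0520 for each). These genes are members of a family of close copies, so their values are uncertain. Hfe, of iron regulation, was at log2 -1.8 ± 0.18 and the F-box gene Fbxo44 at -2.49 ± 0.26 (adjusted p = 0.0520 for each). Colq, the collagen tail of acetylcholinesterase, which fell on denervation, was at 1.10 ± 0.0227 FPKM in DKO-labelled and 3.65 ± 0.575 in denervated WT libraries (-1.69 ± 0.20, adjusted p = 0.0905). Of the rest named by the rule, Ccl27a, Hist1h4i, Serpina3n, Wdr92 and Pkd2 lay higher, at 2.30-fold to 15.5-fold, and Rsph1, Ethe1 and Retnla lower, with adjusted p between 0.106 and 0.140.

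Camera called 7 of 37 lists between DKO-labelled and WT denervated muscle, in none of which a member passed on its own, and with an estimated correlation the adjusted p was 0.995 for each of the 7. Tendon and cartilage markers were higher (median log2 0.63, 9 of 11 above 0, camera adjusted p = 0.00128). The lists of oxidative phosphorylation (median -0.16, 65 genes, adjusted p = 0.00128), the TCA cycle (-0.18, 21 genes, adjusted p = 0.0231), fatty acid use (-0.35, 27 genes, adjusted p = 0.00136) and fast fibres (-0.33, 17 genes, adjusted p = 0.00549) were lower. So were the integrated stress response (-0.28, 17 genes, adjusted p = 0.0107) and red blood cell markers (-1.36, 5 genes, adjusted p = 0.00128). With fry the adjusted p was 0.820 for each. Adjusted over the list alone, 4 of 5 red blood cell markers passed, all lower, and 0 members of the other 6 lists. Denervated WT replicate 1 differed from replicate 2 by a median of 1.5 for tendon and cartilage markers and -1.63 for red blood cell markers.

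Without denervated WT replicate 2 the calls of all these lists but fast fibre genes were lost. The TCA cycle was also lost without each other denervated library, fast fibre genes without denervated WT replicate 1 or DKO-labelled replicate 2, fatty acid use without DKO-labelled replicate 2, and oxidative phosphorylation and the integrated stress response without DKO-labelled replicate 1. The other 30 lists were not called, with camera adjusted p between 0.0955 and 0.987. Among them were neuromuscular junction genes (median -0.01, adjusted p = 0.738), myogenic regulators (-0.05, adjusted p = 0.987), class II histone deacetylase and Dach genes (-0.03, adjusted p = 0.987) and BMP and GDF signalling (-0.07, adjusted p = 0.987). In 8 of the 30, median, mean and test differed in sign.

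The number of genes called between DKO-labelled and WT denervated muscle rested on the fit and on single libraries. In 100 simulated data sets with the same means in both denervated groups, a test added after the data were seen, libraries were drawn independently. There 0 to 5 genes were called between these groups, 0.55 on average, with any call in 35 data sets. Of all tested genes in the real data, 29.8% had both DKO-labelled libraries on 1 side of both denervated WT ones. By chance 33.3% would if libraries were independent, but deviations by run correlated at 0.43 between the denervated groups. The share is therefore no test of a difference. DESeq2 called 182 and limma on log2(FPKM + 0.5) 35, a fit of the 4 denervated libraries called 0, leaving out denervated WT replicate 1 gave 119 and replicate 2 gave 14, and leaving out any other library gave 0 or 1; by edgeR 748 genes had an unadjusted p under 0.05 where 612 would by chance.

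Both comparisons use the denervated WT libraries, so their log2 changes share chance values of opposite sign. Dusp4 was the 1 gene called in both, lower on denervation (log2 -1.71 ± 0.30, edgeR adjusted p = 0.0105) and higher in DKO-labelled libraries. Independent lists of these sizes would share 0.429 genes in that pattern. In the 100 data sets simulated with the denervation effect and no difference between the denervated groups, 0 to 1 genes showed it, 0.13 on average. Each simulation here drew its libraries independently, whereas in the data the deviations by run correlated at 0.21, 0.14 and 0.43 between groups. Across genes the covariance of the 2 sets of changes was -0.04, against -0.06 in 20 simulated data sets with no effect and -0.10 computed from the spread of the denervated WT libraries. The correlation was -0.10, against -0.49 in the same 20 simulated data sets. Those data sets hold no denervation effect, while the real changes on denervation do, so these correlations are not comparable. With a different denervated WT library in each comparison, the covariance was -0.03 one way round and 0.15 the other. Whether denervation acts differently in the knockout was not tested, since it needs innervated knockout muscle.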

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

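DESeq2 and the authors' external scale were alternatives chosen after the data were seen. The others were marked as planned, but most vary the edgeR fit, which was adopted only once the files were found to hold counts. Between denervated and innervated WT muscle, the counts of higher and lower genes stayed within 1.5 times of 1759 and 1753 in every alternative but those that leave out 1 library, which gave 83 to 2610 higher and 119 to 2747 lower. Where 1 library of a group is left out, the lone one is assumed to vary like the other groups. Of 2855 values of the other named genes over these alternatives, 2551 kept the direction and the side of the threshold, 304 lost the call and 0 turned direction. Of the 304, 255 came from leaving out a library, and 201 of those from an innervated one. No scaling tried moved the median of all genes by over 0.1. TMM, median ratio and quantile scaling hold most genes level by design, so this is no test of the balance between higher and lower genes. Scaling by plain library totals was not run.

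Between DKO-labelled and WT denervated muscle, 3 genes were higher, 2 lower, and 1 was called in both comparisons with opposite directions. In that order, limma gave 17, 18 and 17, limma with a pseudocount of 0.1 gave 11, 14 and 13, with 1 it gave 16, 18 and 17, and with quantile normalization 14, 16 and 15. No filter gave 29, 31 and 17, median ratio scaling 5, 5 and 3, and DESeq2 81, 101 and 59. With only the 4 libraries of a comparison it was 0, 0 and 0, for which edgeR in the full fit had 748 genes at an unadjusted p under 0.05. Mean FPKM of at least 2 gave 0 lower genes, with fewer genes tested, and no value for Dach2 or Hdac9; the authors' external scale gave 1 lower. Leaving out 1 library gave 0 to 45 higher, 0 to 74 lower and 0 to 80 in both. The cause was not tested.

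Gene lists called went from 25 to 0 with an estimated correlation and to 11 with fry for denervation, and from 7 to 0 and to 0 for DKO-labelled muscle, where leaving out 1 library gave 6 to 12. Of the 25, 16 were called in all 19 alternatives that kept camera and its preset correlation, and of the 7, 0 were.

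On denervation, Hdac9 ran from -3.65 to -0.97 and Myog from 4.09 to 5.85 with 1 library left out. In DKO-labelled muscle Hdac9 ran from -2.59 to 0.28 and Myog from -0.59 to 1.17, with Hdac9 at 0.28 and Myog at -0.59 without denervated WT replicate 1 and Myog at -0.32 without DKO-labelled replicate 2. The cause was not tested. Dach2 and Gdf5 kept direction and side in each alternative that gave a value.

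The runs of sample numbers are not stated to pair libraries, and with 2 per group the deviations from the group means correlated at 0.21, 0.14 and 0.43 between groups. With the runs as a replicate block, 2134 genes were higher and 2327 lower on denervation, Hdac9 was at -2.2 with an adjusted p of 0.022 (0.008 to 0.386 over its alternatives), and in DKO-labelled muscle 3 were higher, 1 lower and 2 in both, with 2 of the 3 higher and 1 of the 2 lower genes kept. A filter on a status column was not run, since the tables hold none. With 2 libraries per group, the test recovered 19.2% of simulated 2-fold changes for DKO-labelled against WT (12206 genes, 200 of them changed). Most changes of that size were missed there, and in the data such changes can also be missed.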

Other observations

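The genes and tests in this part were all chosen after the results were seen. On denervation, Hes6, a helix-loop-helix factor of muscle differentiation, rose from 16.1 ± 1.36 to 162 ± 1.8 FPKM (SD, n = 2; log2 3.43 ± 0.15, edgeR adjusted p = 0.000598), and the carboxylesterase Ces2c from 0.666 ± 0.0981 to 43.2 ± 10.3 (6.12 ± 0.28, adjusted p = 0.000598). The alpha-1B adrenergic receptor Adra1b rose by 4.95 ± 0.37 (adjusted p = 0.00177), the cation-transporting ATPase Atp13a3 by 3.92 ± 0.33 (adjusted p = 0.00221) and the adaptor protein Blnk by 4.38 ± 0.37 (adjusted p = 0.00224). The secreted guidance factors Sema3f and Sema3b rose by 2.52 ± 0.22 and 2.34 ± 0.18 (adjusted p = 0.00225 and 0.00193). Stbd1, which binds glycogen, rose by 3.51 ± 0.26 (adjusted p = 0.00177) and stood at 156 ± 9.31 FPKM in DKO-labelled against 81 ± 25.7 in WT denervated libraries (adjusted p = 0.444). Hes6 stood at 84 ± 4.88 FPKM in DKO-labelled libraries (-0.90 ± 0.14, adjusted p = 0.177).

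Other genes fell with denervation. The secreted peptide gene Ostn went from 40.9 ± 3.96 to 3.46 ± 0.95 FPKM (SD, n = 2; log2 -3.56 ± 0.24, edgeR adjusted p = 0.00176) and Fndc5, the precursor of irisin, from 88.8 ± 15.4 to 15 ± 0.194 (-2.5 ± 0.17, adjusted p = 0.00176). Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum, fell from 77 ± 5.22 to 2.84 ± 0.359 FPKM (-4.67 ± 0.20, adjusted p = 0.000598). The sodium channel subunit Scn4b was at -4.13 ± 0.40 (adjusted p = 0.00277), the receptor component Ramp1 at -3.56 ± 0.27 (adjusted p = 0.00177), the contractile regulator Smtnl1 at -2.9 ± 0.16 (adjusted p = 0.00108), and the muscle-restricted ribosomal protein Rpl3l at -2.4 ± 0.16 (adjusted p = 0.00176) while Rpl3 rose 8.15-fold. Tpt1 lay at 419, 617 and 619 FPKM in the first library of innervated WT, denervated WT and DKO-labelled muscle and at 29.1, 38.7 and 118 in the second, and the files list Tpt1p over the same coordinates.

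Extracellular matrix genes lay higher in denervated WT replicate 1 than in replicate 2, by a median log2 of 1.66, at 28 of 29 members. A difference between the runs of sample numbers may contribute, since at least 25 members were also higher in the first library of each other group. As the whole cause at 1 size in every group it would leave no excess, and the median excess in denervated WT was 1.02, with quartiles of 0.09 and 1.61. That does not decide the question, since the list was examined after its difference in that group was seen. Its genes also move together, at an estimated correlation of 0.713 in the denervation comparison, so members are not independent. A lower share of fibroblasts in replicate 2 stays open: 10 progenitor markers that are not matrix genes differed by a median of 0.96 (permutation p = 0.141 against the matrix genes). The labels put both libraries in 1 group, so beyond this difference in cell share no biological explanation was tested.

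The genes that differ most between DKO-labelled and WT denervated muscle could reflect segments of another strain's chromosomes carried with the deletions. Segments near the deleted genes are argued against as the whole cause, since within 20 Mb of Hdac9 and Dach2 lay 4 genes of unadjusted p under 0.01, against 3 expected (one-sided Fisher exact p = 0.361), and 0 of the 5 called genes. Segments elsewhere cannot be told apart from an effect of the genotype, because all DKO-labelled libraries share it. In all, 5 neighbouring pairs of different families were found against a mean of 2.6 in 10000 random gene sets (permutation p = 0.129). These include the called genes Dusp4, with Mfhas1 on chromosome 8, and 1700066B19Rik, with Gm6724 on chromosome 18. The others join A930015D03Rik with H2-Q1, H2-Q2 and H2-T10. On chromosome 17, 5 of the 137 genes tested between 33 and 38 Mb had an unadjusted p under 0.001, in a window drawn around H2-K1, H2-Q1 and H2-Q2, so their closeness goes with a segment but does not test for one. Fragments shared among class I copies are argued against for H2-K1. The summed loss of 17 other copies was -5.1% of what H2-K1 gained, a gain and not a loss. An effect of the genes labelled as deleted stays open and untested.

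Rpl35 fell 89.2-fold on denervation while 57 of 60 ribosomal protein genes rose. Reads shared with copies of Rpl35 may account for it, a possibility these files cannot test. The first search for copies used the whole transcript and found 0. The search was then changed to the coding sequence and found 6 copies in GRCm38, with matches allowed to fall short of full identity and length. The files list 0 of them under their own names, so reads shared with copies of Rpl35 cannot be told apart from a real fall, and an effect of denervation stays open and untested.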
